A study of Mus musculus with 52 samples.

How the data were processed

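The study measured nuclear RNA, H3K27ac and chromatin contacts in sensory neurons of mouse dorsal root ganglia. Wild-type animals (WT) carried the INTACT allele, which marks nuclei of Cre-expressing cells with GFP, and Advillin-Cre, a driver active in sensory neurons. Knockout animals (KO) carried in addition a conditional allele of Scc1, the older name of the cohesin subunit gene Rad21. Animals were naive, sham-operated or given a crush of the sciatic nerve. Per the labels' protocols, tissue was taken 3 days after surgery and 14 days after tamoxifen, which activates the Cre. The series holds 52 samples, of which 16 are Hi-C, 12 promoter Hi-C and 6 H3K27ac samples, and 18 RNA-seq libraries in 6 groups of 3. The 18 RNA-seq libraries and the H3K27ac peak lists of WT sham and WT crush were analysed. Contact maps were not analysed here.

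Per the labels' protocols, GFP-marked nuclei were isolated on antibody-coated beads, RNA was purified with DNase treatment, ribosomal RNA was depleted and libraries were made with a kit that keeps strand. The deposited counts are whole-number read counts per gene over exons, made with HISAT2 and featureCounts on build mm10 per the submitters' processing notes. Tool versions, the strand setting, multi-mapping and duplicate handling are not given in the sources used here. Because the strand setting is not stated, reads of a gene and of a partner on the opposite strand may not be separated. Of 129 genes named, 55 overlap a gene model on the opposite strand and 34 overlap a model on the same strand. Values of genes with a named overlapping neighbour are therefore uncertain. Those on the opposite strand or sharing exons include Aaed1, Cebpb, Cx3cr1, Flrt3, Glb1l2, Gt(ROSA)26Sor, H19, Hoxb5, Igfbp7, Insrr, Irf7, Jun, Kcnh1, Lamb3, Lin7b, Lrrtm2, Lrrtm3, Lypd1, Prss41, Stat5a and the clustered protocadherins. Members of multigene families and pseudogenes, such as Ifit1, Slfn9, Mrgprb5, Mrgprx1 and Atp6v0c-ps2, are uncertain as well, since reads can be split among near-identical copies.

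The deposited H3K27ac lists give a total and a maximum signal of fragment coverage per peak. They come from Cut&Tag of NeuN-sorted nuclei, processed with Trim Galore and Bowtie2 on mm10 per the submitters' processing notes. Per the file names, peaks were called with SEACR in stringent mode with a cut to a top share. Each list joins the peaks of a reference set with overlapping peaks of 2 further sets. Whether a set is 1 replicate, a control and the scaling are not given, so signal was not compared between lists. Total signal served only to rank peaks within a list for 1 alternative, and maximum signals and those of the further sets were not used.

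Each count file held 55487 genes, and 55141 IDs were matched to a symbol. No per-sample columns were left out. Total counts were 13951578 to 20056843 in naive libraries and 26005081 to 44981417 in sham and crush libraries, so precision for low genes is lower in the naive groups. Replicates of a group were checked for duplicates with a chi-square test of counts over genes with at least 20 summed counts. It gave 4.98 to 79.43 per gene, where 1 is sampling noise, and no library was merged. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. PCR duplicates were not identified by molecular tags, so intervals and floors cover counting error only.

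Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion, TMM normalisation). Low genes were removed with filterByExpr (minimum count 10, minimum total 15), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Crush against sham, KO against WT after each operation and the genotype by injury interaction came from a single fit of the 12 sham and crush libraries with 4 group means. KO against WT in naive animals used the 6 naive libraries. Sham against naive used all 18 libraries. Levels in CPM (counts scaled to a fixed library total) are given on the TMM-scaled library sizes of the fit concerned, as mean ± SD over 3 libraries, so levels of a gene differ slightly between fits. Plots of genes and Rad21 levels use TMM-scaled totals of all 18 libraries with no filter. Gene coordinates are those of the count files, 1-based, on mm10. An exact 0 over a group was given a floor of 3 counts over that group.

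Of the 30 gene lists, fixed before the data were examined, each was tested with camera in limma 3.58.1 (preset correlation 0.01), with adjustment over the 30 lists of a comparison. They cover regeneration-associated genes, injury transcription factors, immediate early genes, growth cytoskeleton, neuropeptides, sensory channels and receptors, potassium channels, 4 classes of sensory neurons, pan-neuronal markers, satellite glia, Schwann cells, macrophages and other immune cells, endothelial and mural cells, fibroblasts, cohesin and CTCF, the alpha, beta and gamma protocadherins, Hox genes, p53 targets, interferon response, cholesterol synthesis, stress of unfolded proteins, axon guidance, synaptic adhesion, neurotransmitter release and mitochondrially encoded genes. Camera's preset correlation is small. With a correlation estimated from the data, calls held for the alpha, beta and gamma protocadherins and Hox genes in KO against WT (gamma not in naive animals) and for the pruriceptor list in KO sham and KO naive. No call of the crush or sham against naive comparisons held. The 4 classes were nonpeptidergic nociceptors, peptidergic nociceptors, a list of pruriceptors, C-fibre low-threshold and cold-sensing neurons (called the pruriceptor list), and large-diameter neurons.

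The groups, tests, gene lists and most alternatives were also chosen before the data were examined. The rule for genes named in the text took, per comparison, up to 10 genes per direction with the largest change among called genes with an average log2 CPM of at least 2 and no overlap between groups. From each list it added up to 4 called members with the largest change, or 2 abundant members where none was called, plus the cohesin genes. The interaction took the 10 smallest p-values per direction. Genes of unnamed models were left out. From the genes this rule allows, those in the text were picked mostly among genes whose call held without each library in turn, which favours them in the leave-one-out counts.

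An injury score was the mean log2(CPM + 1) of genes called up minus that of genes called down by the average injury effect of both genotypes, and a regeneration-associated score was the mean log2(CPM + 1) of that list. Scores were compared by an exact two-sided permutation of genotype labels within sham and within crush. The intronic share, a measure chosen after seeing the data, is the percent of a library's counts in 3626 single-exon unnamed gene models that lie within another gene on the same strand, and serves as a sign of unspliced RNA. Peaks were compared with bedtools 2.31.1 (overlap of at least 1 bp) and assigned to genes within 50 kb of the start site. Shares were tested with Fisher's exact test, two-sided, and given exact (Clopper-Pearson) 95% intervals. Gene permutation tests used 100000 resamples. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used for the rest.

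Groups share replicate numbers, and it was checked whether libraries with the same number deviate together from their group means over 12858 genes. In crush against sham in WT the correlations were 0.46, 0.67 and 0.72, and in KO against WT after sham they were 0.15, 0.69 and 0.43, so the numbers were taken to pair these libraries from the values alone, since no label states a pairing. Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, other low-count filters, a non-robust dispersion, a replicate block, other libraries in the fit, a 2-fold threshold, each library left out, and for lists a correlation estimated from the data and fry. Added after seeing the data were the intronic share as a covariate, leaving out all libraries with the same number, and other definitions of peaks. The tests were also tested on simulated data with 200 genes changed, all with an average log2 CPM above 2. Counts were drawn independently for each gene. With edgeR, crush against sham in WT recovered 23.9% of genes changed 1.5-fold, 91% of those changed 2-fold and 100% of those changed 4-fold among 22556 genes, and the interaction recovered 1.5%, 49.3% and 97% among 22548 genes. Size factors of DESeq2 moved the median log2 fold change of all genes by at most 0.02.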

Results

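Nuclear RNA of sensory neurons was measured in 18 libraries, 3 in each of 6 groups: naive, sham and crush, each in WT and KO. The KO targets Rad21, a subunit of the cohesin ring that holds chromatin loops, from sensory neurons of adult mice. In WT, naive libraries held 20056843, 15923795 and 14149903 counts, sham libraries 44981417, 40234803 and 33230396, and crush libraries 42031410, 40191002 and 33639089. In KO, naive libraries held 18100324, 13957098 and 13951578 counts, sham libraries 29427999, 36497860 and 26005081, and crush libraries 41312284, 35207522 and 39598395. Mitochondrially encoded genes took 0.413% to 0.83% of counts. The intronic share, a sign of unspliced RNA, was 0.34% ± 0.11 (SD, n = 3) in naive WT, 0.5% ± 0.17 in naive KO, 0.93% ± 0.18 in sham WT, 0.79% ± 0.29 in crush WT, 1.15% ± 0.35 in sham KO and 0.77% ± 0.24 in crush KO.

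Rad21 (ENSMUSG00000022314, chromosome 15, 51962240 to 51991747) fell in KO in every condition. Its level was 74 ± 9.92 CPM (n = 3) in naive WT and 22.7 ± 0.551 in naive KO, 73.5 ± 1.59 in sham WT and 21.9 ± 0.252 in sham KO, and 77.8 ± 13.1 in crush WT and 21 ± 3.87 in crush KO. All 9 KO libraries lay below all 9 WT libraries. The log2 fold change was -1.68 in naive (SE 0.114, adjusted p = 0.000138), -1.74 after sham (SE 0.139, adjusted p = 1.78e-05) and -1.89 after crush (SE 0.139, adjusted p = 7.05e-06). Counts over the whole gene may include exons outside the deleted part. Of the cohesin and CTCF genes tested, Stag1 (an alternative cohesin subunit) rose and Pds5b (a cohesin regulator) fell in KO in the 3 conditions, with log2 fold changes of 0.68, 0.65 and 0.59 for Stag1 and -0.48, -0.52 and -0.43 for Pds5b in naive, sham and crush. Their adjusted p was 0.0223, 0.00751 and 0.0116 for Stag1 and 0.0299, 0.00284 and 0.00834 for Pds5b. The list as a whole passed camera in none of the 3 (adjusted p = 0.493, 0.707 and 0.495). With 1 library left out some of these calls were lost at folds of similar size, 0.53 for Stag1 after crush, 0.56 to 0.75 for Stag1 in naive and -0.44 to -0.51 for Pds5b in naive. The Stag1 call after crush was lost without crush WT library 1 (adjusted p = 0.0698), and in naive without WT library 1, 2 or 3 (0.0716, 0.0513 and 0.0733) or KO library 1 (0.0598). The Pds5b call in naive was lost without WT library 1 or 3 (0.102 and 0.163) or KO library 1 or 2 (0.14 and 0.083), and with the replicate block.

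**Figure D1:**
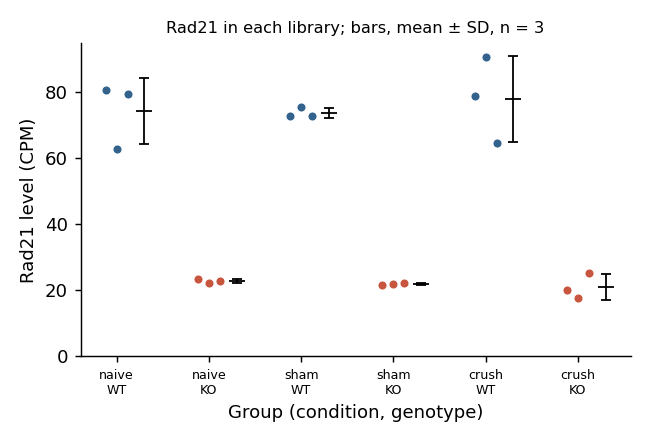
Rad21 level in CPM of TMM-scaled totals (y axis) in each of 18 libraries by condition and genotype (x axis); points are libraries and bars give the mean and SD of 3. KO group means lie at 21 to 22.7 CPM and WT group means at 73.5 to 77.8 CPM.

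Crush was compared with sham in WT to ask how sensory neurons respond to nerve injury. Among genes that rose were neuropeptides and genes of regrowing axons. Npy, a neuropeptide (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507), was 35.1 ± 17.3 CPM after crush and 3.13 ± 1.45 after sham (n = 3 each), 11.1-fold higher with a log2 fold change of 3.48 (SE 0.494, adjusted p = 0.00163). Sprr1a, which promotes axon outgrowth (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), was 143 ± 74.5 against 16.2 ± 3.35 CPM, 8.81-fold higher (log2 3.14, SE 0.371, adjusted p = 0.000621). Atf3, a transcription factor induced by axon injury (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), was 304 ± 76.9 against 49.5 ± 13.1 CPM, 6.14-fold higher (log2 2.62, SE 0.35, adjusted p = 0.00112). Gal, the neuropeptide galanin (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544), was 195 ± 47.1 against 32.6 ± 9.51 CPM, 5.98-fold higher (log2 2.58, SE 0.364, adjusted p = 0.00154). Other genes with large rises were Slfn9 (7.25-fold), the receptor gene Gpr151 (6.44-fold), the tubulin Tubb6 (5.72-fold), the receptor Acvr1c (5.54-fold) and the neuropeptide Nts (4.85-fold), with adjusted p from 0.000253 for Slfn9 to 0.00211 for Tubb6. Genes that fell changed less. Ybx2, an RNA-binding protein gene (ENSMUSG00000018554, chromosome 11, 69935796 to 69941605), was 1.89 ± 0.249 CPM after crush and 5.71 ± 1.27 after sham (log2 -1.59, SE 0.231, adjusted p = 0.00177). Vstm2b fell by 1.49 on the log2 scale, the axonemal dynein gene Dnah6 by 1.44, Glb1l2 by 1.38, the nuclear receptor gene Esrrg by 1.15, Galm by 1.14 and Lin7b by 1.1, with adjusted p from 0.000222 for Galm to 0.00111 for Dnah6.

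In all, 745 genes rose and 354 fell of 23112 tested in WT, of which 401 and 71 changed at least 2-fold. The groups did not overlap for any of the 1099, which choosing genes from the same libraries favours. Without sham library 1, 2 or 3 the count was 546, 704 or 611 genes, and without crush library 1 or 2 it was 529 or 656. With a replicate block over 12 libraries, not all paired, 4193 genes were called, and all 1099 kept their direction. With all libraries numbered 1 left out, which leaves 2 per group, 9 genes were called.

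Regeneration-associated genes rose as a group in WT. Of 42 tested members 35 rose and none fell (41 and 0 adjusted over the list alone), and all 42 were higher after crush, with a median log2 fold change of 1.55. The camera adjusted p was 7.18e-87, and adjusted p = 0.0557 with an estimated correlation. Among injury transcription factors, 11 of 26 rose (16 rose and 1 fell, adjusted over the list alone), including Sox11 at 293 ± 41.1 against 100 ± 13.0 CPM (log2 1.55, SE 0.186, adjusted p = 0.000682), Jun (log2 1.39, adjusted p = 0.00843) and Nfil3 (log2 1.66, adjusted p = 0.000412). Their camera adjusted p was 2.3e-16, and adjusted p = 0.0876 with an estimated correlation. Of 24 growth cytoskeleton genes 4 rose and 1 fell (11 and 2 adjusted over the list alone). Gap43, a growth cone protein gene, rose 3.06-fold (adjusted p = 0.0084) and Stmn4, a tubulin-binding protein gene, rose 4.02-fold (adjusted p = 0.000449). The list gave 2.19e-06 by camera, and adjusted p = 0.362 with an estimated correlation. Of 14 neuropeptide genes 6 rose (6 adjusted over the list alone), among them Grp, which went from 0.0812 ± 0.0489 to 1.28 ± 0.644 CPM (log2 3.89, SE 0.637, adjusted p = 0.00385). Neuropeptides gave 2.82e-06 by camera, and adjusted p = 0.271 with an estimated correlation. The intronic share, with which growth cytoskeleton, neuropeptide and regeneration-associated genes moved oppositely within groups, averaged 0.93% ± 0.18 in sham WT and 0.79% ± 0.29 in crush WT.

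Some genes of stress programmes rose in WT and some channel and adhesion genes fell, though none of the lists in this group kept its call with an estimated correlation. Of 20 p53 targets 4 rose (6 adjusted over the list alone), among them the growth arrest gene Gadd45a (3.87-fold, adjusted p = 0.000693), the cell cycle inhibitor Cdkn1a (2.96-fold, adjusted p = 0.000814), Sesn2 (1.82-fold, adjusted p = 0.00486) and Btg2 (1.93-fold, adjusted p = 0.00509). Camera gave 5.03e-06 for p53 targets, and adjusted p = 0.0876 with an estimated correlation. Genes of unfolded protein stress (2 of 20 rose, 7 adjusted over the list alone) and cholesterol synthesis (1 of 19 rose, Hsd17b7, 2.51-fold, also 1 adjusted over the list alone) gave 2.82e-06 and 2.01e-05, and adjusted p = 0.271 and 0.362 with an estimated correlation. Interferon response genes (3 of 24 rose, 10 adjusted over the list alone) gave 4.09e-06, and adjusted p = 0.277 with an estimated correlation; Usp18, an interferon-induced protease gene, was 2.74 ± 0.162 against 0.954 ± 0.176 CPM (adjusted p = 0.00356). Of immediate early genes 1 of 15 rose (2 adjusted over the list alone), with 0.0148 by camera, adjusted p = 0.274 with an estimated correlation and 0.0545 without sham library 1. Of 32 sensory channels and receptors 5 fell (7 adjusted over the list alone), among them the cold channel gene Trpm8 and the sodium channel gene Scn1a, both with log2 fold changes of -0.72 (adjusted p = 0.00636 and 0.00221). Of 32 potassium channel genes 8 fell (13 adjusted over the list alone). Both lists passed camera (2.15e-05 and 1.39e-07), and adjusted p = 0.271 with an estimated correlation in both. Of 34 synaptic adhesion genes 6 fell and 1 rose (11 and 2 adjusted over the list alone), with Cntn5 at a log2 fold change of -0.81 and Lrrtm3 at 1.21 (adjusted p = 0.00154 and 0.000462). The list gave 1.58e-05, and adjusted p = 0.152 with an estimated correlation. Of 15 large-diameter neuron genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with Etv1 at -0.86 and Spp1 at 1.24. The list gave 0.000556, adjusted p = 0.362 with an estimated correlation and 0.083 without crush library 3.

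Some markers of other cells were also higher after crush in WT. Of 16 macrophage and immune genes 10 rose (14 adjusted over the list alone), with a median log2 fold change of 1.22. The complement gene C1qa was 7.17 ± 0.633 against 2.54 ± 0.392 CPM (log2 1.5, SE 0.227, adjusted p = 0.0023) and the receptor gene Cx3cr1 rose 2.78-fold (adjusted p = 0.00593). Camera gave 3.44e-18, and adjusted p = 0.0876 with an estimated correlation. Of 12 fibroblast genes 2 rose (6 adjusted over the list alone), with 0.000214 by camera and adjusted p = 0.362 with an estimated correlation. Endothelial and mural genes (0 of 14 called, 1 rose adjusted over the list alone) gave 0.0367 by camera, adjusted p = 0.679 with an estimated correlation, 0.0949 with the replicate block, 0.48 without sham library 1 and 0.362 without crush library 3. Satellite glia and Schwann cell lists had 0 called members (1 and 0 adjusted over the list alone, camera adjusted p = 0.127 and 0.512). The other 11 lists passed neither way by camera, namely nonpeptidergic, peptidergic and pruriceptor neurons (0.129, 0.381 and 0.0883), pan-neuronal markers (0.637), cohesin (0.637), alpha, beta and gamma protocadherins (0.853, 0.853 and 0.256), Hox genes (0.0883), neurotransmitter release (0.365) and mitochondrially encoded genes (0.308). Axon guidance genes went both ways, with 4 of 36 up and 3 down (5 and 4 adjusted over the list alone, camera adjusted p = 0.637). Among them the semaphorin gene Sema6a rose 4.2-fold (329 ± 72.5 against 78.3 ± 16.1 CPM, adjusted p = 0.000462) and the ephrin receptor gene Epha3 rose 3.3-fold (adjusted p = 0.000693).

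The same comparison in KO asked whether neurons with less Rad21 RNA respond to injury. Npy was 51.9 ± 11.6 CPM after crush and 6.09 ± 3.9 after sham, 8.5-fold higher (log2 3.09, SE 0.478, adjusted p = 0.00275). Sprr1a was 83.4 ± 22.8 against 11.6 ± 4.12 CPM (7.16-fold, SE 0.372 on the log2 scale, adjusted p = 0.00121), and Atf3 was 254 ± 71.5 against 43.6 ± 18.8 CPM (5.83-fold, SE 0.35 on the log2 scale, adjusted p = 0.00149). Slfn9 rose 7.25-fold, Gpr151 6.57-fold, Gal 6.11-fold, Tubb6 5.82-fold, Anxa1, an annexin gene, 5.67-fold and Procr, the protein C receptor gene, 5.44-fold, with adjusted p from 0.000462 for Slfn9 to 0.00242 for Tubb6. Among genes that fell, Vstm2b had a log2 fold change of -1.84, Dnah6 of -1.79, L3mbtl4 of -1.43, Ybx2 of -1.33 and Csmd3 of -1.15 (adjusted p from 0.000462 for Vstm2b to 0.00742 for Csmd3). Atp6v0c-ps2, a pseudogene and so uncertain, was 27 ± 23.2 against 0.537 ± 0.19 CPM (adjusted p = 0.0113), a call lost without sham library 1 or 3 (0.0539 and 0.0617). In all, 812 genes rose and 437 fell in KO, of which 438 and 122 changed at least 2-fold. Without sham library 1 or 3 the count was 661 or 520 genes, without crush library 1 or 2 it was 537 or 566, and without crush library 3 it was 2369. With all libraries numbered 1 left out it was 36, and fitted on the 6 KO libraries alone it was 574.

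Regeneration-associated genes rose in KO as well. Of 42 members 35 rose and none fell (40 and 0 adjusted over the list alone), with a median log2 fold change of 1.36. Camera gave 6.42e-64, and adjusted p = 0.11 with an estimated correlation. Sox11 rose 3.28-fold, Gap43 3.54-fold, Stmn4 2.95-fold and Sema6a 2.87-fold, and the cytokine gene Il6 went from 0.282 ± 0.126 to 1.81 ± 0.44 CPM (adjusted p = 0.00485). Injury transcription factors (9 of 26 rose, 14 adjusted over the list alone), growth cytoskeleton (3 rose and 1 fell of 24, 11 and 1 adjusted over the list alone) and neuropeptides (5 of 14 rose, 6 rose and 1 fell adjusted over the list alone) gave 1.16e-11, 5.64e-06 and 7.49e-06 by camera, and adjusted p = 0.131, 0.502 and 0.309 with an estimated correlation. Of 24 interferon response genes 15 rose (17 adjusted over the list alone), with a median log2 fold change of 0.99. Ifit1, an interferon-induced gene of a multigene family, was 37.9 ± 9.24 against 11.8 ± 3.06 CPM (log2 1.68, SE 0.269, adjusted p = 0.00347), and Usp18 rose 3.2-fold (adjusted p = 0.00159). Rsad2, the antiviral gene of viperin, rose 3.06-fold (adjusted p = 0.0164), a call lost without sham library 1 or 3 (0.0732 and 0.0818). The interferon list gave 2.98e-17 by camera, and adjusted p = 0.11 with an estimated correlation. Macrophage and immune genes (5 of 16 rose, 9 adjusted over the list alone, median 0.83) gave 3.33e-09, and adjusted p = 0.197 with an estimated correlation. In this comparison the intronic share was 0.77% ± 0.24 after crush and 1.15% ± 0.35 after sham.

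Of 20 p53 targets 5 rose in KO (6 adjusted over the list alone), with the cell death gene Pmaip1 at 4.71-fold, Gadd45a at 3.66-fold and Cdkn1a at 2.97-fold (adjusted p = 0.00163, 0.0011 and 0.0011). The list gave 1.68e-06 by camera, and adjusted p = 0.11 with an estimated correlation. Unfolded protein stress (2 of 20 rose, 7 adjusted over the list alone, Chac1 at 2.38-fold) and cholesterol synthesis (1 of 19 rose, 11 adjusted over the list alone, Hsd17b7 at 2.5-fold) gave 7.49e-06 and 6.03e-07, and adjusted p = 0.309 and 0.399 with an estimated correlation. Synaptic adhesion genes (8 of 34 fell and 1 rose, 16 and 2 adjusted over the list alone) gave 1.89e-05, and adjusted p = 0.131 with an estimated correlation. The contactin gene Cntn5 fell by 1.02 and the adhesion gene Dscam by 0.72 on the log2 scale (adjusted p = 0.000538 and 0.00394). Sensory channels (5 of 32 fell, 8 fell and 1 rose adjusted over the list alone) gave 0.00127, adjusted p = 0.439 with an estimated correlation and 0.0855 without crush library 3. The acid-sensing channel gene Asic3 was 67.2 ± 17.7 against 142 ± 6.89 CPM (adjusted p = 0.0018), and the potassium channel gene Kcnk18 fell by 1.12 (adjusted p = 0.0142). Potassium channels (4 of 32 fell, 7 fell and 1 rose adjusted over the list alone) gave 0.00512, adjusted p = 0.736 with an estimated correlation, and 0.183 and 0.36 without sham library 2 and crush library 3; with the intronic share as a covariate 15 fell, with a median of -0.32 against -0.11. Hox genes (0 of 32 called) gave 0.0129, adjusted p = 0.11 with an estimated correlation and 0.139 without crush library 3. Fibroblast genes (1 of 12 rose, Apod at 2.11-fold, 2 adjusted over the list alone) gave 0.0229, adjusted p = 0.736 with an estimated correlation, and 0.164, 0.0611, 0.0572 and 0.0755 without sham library 1, sham library 3, crush library 2 and crush library 3. No call was made by camera for the other 16 lists. Within them, Unc5b, a netrin receptor gene, fell by 0.99, Whrn, a large-diameter list member, by 1.0 and Etv1 by 0.59 on the log2 scale.

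Of the genes called in WT, 464 were also called up and 183 called down in KO, against 26.2 and 6.7 for independent lists, and none was called in opposite directions. The 2 comparisons share no library. Of the WT calls, 97.6% of those up and 98.9% of those down had the same sign in KO.

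**Figure D2:**
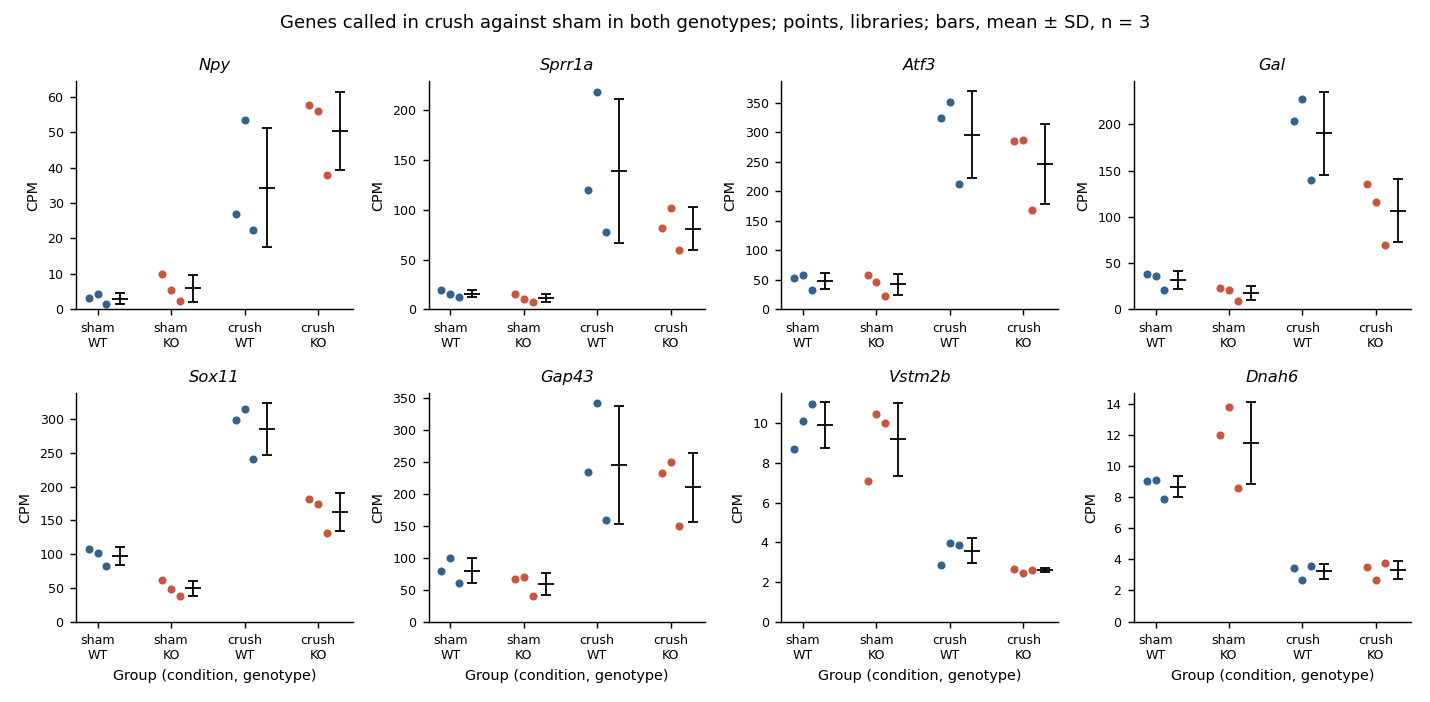
Level in CPM of TMM-scaled totals (y axes) of 8 genes in the sham and crush groups of WT and KO (x axes); points are libraries and bars give the mean and SD of 3. Npy, Sprr1a, Atf3, Gal, Sox11 and Gap43 are higher, and Vstm2b and Dnah6 lower, in every crush library than in every sham library of the same genotype.

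Whether the response differed between genotypes was tested directly as the interaction. No gene passed the edgeR test (0 up and 0 down of 23112), 699 genes had an unadjusted p under 0.05, and DESeq2 called 12 up and 22 down. The replicate block called 46 genes and the intronic share as a covariate 58, among them 2 and 3 regeneration-associated genes, each with a smaller response in KO. Without crush KO library 3 edgeR called 3 genes. The smallest adjusted p was 0.264, for Stat5a, a gene that overlaps Stat3 on the opposite strand (log2 difference -1.0, SE 0.151). Man1a had -0.88 (SE 0.142, adjusted p = 0.288), and Wnt5a, Tnr, Tll1, Caln1, Neto1 and Nabp1 had 0.86, 1.35, 0.88, 1.16, -1.15 and -0.83, all with adjusted p = 0.405. All 8 passed with DESeq2, the covariate (adjusted p under 0.01) and the replicate block (under 0.03). DESeq2 is weak support here, since on simulated data of this design 43 of its 162 calls were false, against 11 of 109 with edgeR. There edgeR recovered 49.3% of genes that differed 2-fold, so many differences of that size or smaller would be missed. The injury score rose from sham to crush by 0.958 in WT and 1.035 in KO, and the difference between genotypes was 0.077 (SE 0.227; exact permutation p = 0.73, 400 permutations, smallest possible 0.005). The regeneration-associated score rose by 1.437 in WT and 1.371 in KO, a difference of -0.066 (SE 0.301; exact permutation p = 0.845). The list's median interaction was -0.082, or -0.222 with the covariate. By camera 7 of 30 lists passed the threshold in the interaction, and 0 did with an estimated correlation. The count was 1 without sham WT library 1, 4 without sham KO library 1 and 2 without crush KO library 2. The interferon list kept its call without each of the 12 libraries. For 22 of its 24 members the difference was above 0, toward a larger response in KO (median log2 difference 0.35, camera adjusted p = 2.31e-08, adjusted p = 0.934 with an estimated correlation). The difference of its score was 0.365 (SE 0.17; exact permutation p = 0.24). No score p tests the difference alone.

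**Figure D3:**
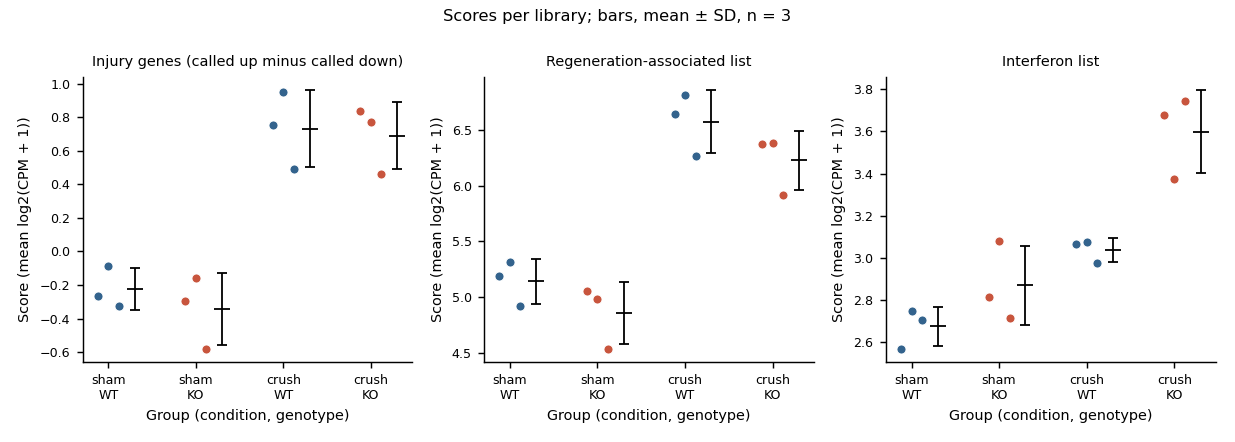
Injury score, regeneration-associated score and interferon score (y axes, mean log2(CPM + 1)) per library in sham and crush groups of WT and KO (x axes); points are libraries and bars give the mean and SD of 3. The regeneration-associated score averages 5.139 and 6.576 in sham and crush WT, and 4.856 and 6.227 in sham and crush KO.

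KO was compared with WT after sham to ask which genes differ with less Rad21 RNA in adult sensory neurons. The clustered protocadherins fell, as did some genes of channels, receptors and neuropeptides. Kcnf1, a potassium channel subunit gene (ENSMUSG00000051726, chromosome 12, 17172100 to 17176888), was 0.61 ± 0.297 CPM in KO and 24.4 ± 3.38 in WT (n = 3 each), a log2 fold change of -5.28 (SE 0.297, adjusted p = 1.9e-06). Lypd1 (ENSMUSG00000026344, chromosome 1, 125867622 to 125913101, overlapping Gpr39 and so uncertain) was 0.314 ± 0.168 against 9.84 ± 1.57 CPM (log2 -4.91, SE 0.409, adjusted p = 2.55e-05). Calb1, the calcium-binding protein calbindin (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064), was 1.71 ± 0.602 against 21 ± 1.9 CPM (log2 -3.61, SE 0.226, adjusted p = 2.42e-06). Shisa9, the serotonin transporter gene Slc6a4, the transcription factor gene Insm1, the receptor gene Insrr and the itch receptor gene Mrgprb5 had log2 fold changes of -3.86, -3.8, -3.46, -3.36 and -3.22 (adjusted p from 1.9e-06 for Insm1 to 0.000109 for Mrgprb5). Prss41 and the pseudogene Atp6v0c-ps2 had -5.49 and -5.78 (adjusted p = 0.00406 and 0.0104); the call of the pseudogene was lost without sham KO library 1 or 3 (0.0617 and 0.0503). Fewer genes rose, and by less. Chia1, a chitinase gene (ENSMUSG00000062778, chromosome 3, 106113229 to 106132120), was 19.8 ± 2.57 against 6.94 ± 1.18 CPM (log2 1.51, SE 0.178, adjusted p = 0.000326). Plpp4, Aaed1, Gt(ROSA)26Sor and Catspere2 rose 2.77, 2.69, 2.65 and 2.61-fold. The INTACT allele is usually carried at Gt(ROSA)26Sor, so its value is uncertain.

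After sham, 238 genes rose and 681 fell in KO, and 492 of them changed at least 2-fold. All 919 genes had groups without overlap, which choosing them from the same libraries favours. Without sham WT library 1, 2 or 3 the count was 520, 514 or 601 genes, and without sham KO library 1 or 3 it was 452 or 600. With the replicate block 2549 genes were called, 914 of the 919 among them with the same direction.

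The clustered protocadherins, cell surface proteins encoded in 3 tandem arrays on chromosome 18, fell together after sham. All 21 tested beta members fell (21 adjusted over the list alone), as did 21 of 22 gamma members (22) and 9 of 13 alpha members (11), with median log2 fold changes of -1.61, -1.38 and -1.41. The camera adjusted p was 1.95e-113, 1.29e-66 and 6.5e-34, and 0.000132, 0.00271 and 0.000491 with an estimated correlation. Pcdhb18 (ENSMUSG00000048347, chromosome 18, 37489465 to 37494505) was 2.87 ± 0.522 CPM in KO and 15.8 ± 0.45 in WT (log2 -2.46, SE 0.149, adjusted p = 2.04e-06), and Pcdhb22 had -2.4. Pcdha12, Pcdha9, Pcdhga2 and Pcdhga3, whose models share exons with the rest of their array, had -2.34, -2.19, -2.1 and -2.02. Hox genes moved the other way, with 8 of 32 up and 1 down (16 and 2 adjusted over the list alone), a median of 0.49 and a camera adjusted p of 9.64e-07, or 0.00271 with an estimated correlation. Hoxc4 was 31.5 ± 5.55 against 16.4 ± 1.92 CPM (adjusted p = 0.00677).

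Of 12 pruriceptor list genes 4 fell after sham (6 adjusted over the list alone, camera adjusted p = 2.26e-06, adjusted p = 0.0478 with an estimated correlation), among them Th, tyrosine hydroxylase (34.8 ± 5.06 against 86.6 ± 8.67 CPM, log2 -1.32, SE 0.175, adjusted p = 0.000846). Peptidergic nociceptor genes (6 of 12 fell, 8 fell and 1 rose adjusted over the list alone) and large-diameter genes (2 of 15 fell, 5 adjusted over the list alone) gave 5.17e-08 and 9.64e-07, and adjusted p = 0.136 and 0.237 with an estimated correlation. Of 14 neuropeptide genes 4 fell (8 fell and 1 rose adjusted over the list alone), with 1.32e-05 by camera and adjusted p = 0.278 with an estimated correlation. Crh and Tac1, the substance P precursor gene, had log2 fold changes of -3.39 and -1.31 (adjusted p = 0.000733 and 0.00108). Of 32 potassium channel genes 9 fell (13 fell and 1 rose adjusted over the list alone), with Kcnd2 at -3.53, Kcnq3 at -2.17 and Kcnh1 at -1.41, and camera gave 2.21e-10, and adjusted p = 0.195 with an estimated correlation. Sensory channels (4 of 32 fell, 6 fell and 1 rose adjusted over the list alone, the cannabinoid receptor gene Cnr1 at -1.84) gave 0.0146, adjusted p = 0.599 with an estimated correlation, and 0.0576 and 0.0962 without sham WT library 2 and sham KO library 3.

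Some regeneration-associated genes were lower in KO after sham. Of 42 members 5 fell (10 fell and 3 rose adjusted over the list alone), with a median of -0.2, 8.41e-05 by camera, adjusted p = 0.787 with an estimated correlation and 0.116 without sham KO library 3. Flrt3, the endopeptidase gene Ecel1, Sez6l and Sema6a had log2 fold changes of -2.1, -1.79, -1.65 and -1.28. The intronic share was 1.15% ± 0.35 in sham KO and 0.93% ± 0.18 in sham WT, and with it as a covariate the median was -0.07, with 9 members down and 5 up. Axon guidance genes (7 of 36 fell and 1 rose, 11 and 1 adjusted over the list alone) gave 1.03e-05, and adjusted p = 0.136 with an estimated correlation, with the receptor genes Plxna2 at -1.2 and Nrp1 at -1.02 (adjusted p = 0.000565 and 5.61e-05). Interferon genes (0 of 24 called, 2 rose adjusted over the list alone, median 0.28) gave 0.00169, adjusted p = 0.599 with an estimated correlation and 0.195 without sham KO library 2. The other lists gave no camera call, including satellite glia (0.206), Schwann cells (0.475), macrophages (0.998), endothelial cells (0.888) and fibroblasts (0.478). With a replicate block 4 interferon genes rose. Injury transcription factors and neurotransmitter release passed with it (0.0439 and 0.0124, against 0.351 and 0.475 without, or 0.977 each with an estimated correlation). Cplx2, a release gene, was 83.1 ± 20.3 against 204 ± 43.6 CPM (adjusted p = 0.00743), and Plk2, a p53 target, fell by 1.08 on the log2 scale.

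After crush, genes that fell in KO included Kcnf1 (0.538 ± 0.182 against 20.5 ± 4.13 CPM, log2 -5.23, SE 0.296, adjusted p = 1.1e-06) and Lypd1 (log2 -4.84, SE 0.403, adjusted p = 1.79e-05). Inhbb, an activin subunit gene (ENSMUSG00000037035, chromosome 1, 119415465 to 119422248), was 2.97 ± 0.714 against 44.5 ± 9.25 CPM (log2 -3.91, SE 0.219, adjusted p = 1.1e-06). Flrt3, inside an intron of Macrod2 and so uncertain, was 22.7 ± 4.34 against 195 ± 36.8 CPM (log2 -3.1, SE 0.205, adjusted p = 2.92e-06). Shisa9, Mrgprb5, Insrr, Calb1, Slc6a4 and the transcription factor gene Mycn had log2 fold changes of -4.24, -3.92, -3.64, -3.44, -3.38 and -3.37. Lamb3, a laminin gene, rose 4.36-fold, Plpp4 3.96-fold, Tmc5 3.67-fold, Aaed1 3.13-fold, the plexin gene Plxnc1 2.82-fold and Gt(ROSA)26Sor 2.78-fold (adjusted p from 1.1e-06 for Aaed1 to 0.00608 for Tmc5). In all, 359 genes rose and 744 fell, of which 149 and 420 changed at least 2-fold. Without crush WT library 1 the count was 596 genes and without crush KO library 2 it was 627.

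After crush 21 of 21 beta (21 adjusted over the list alone), 20 of 22 gamma (22) and 10 of 13 alpha (10) protocadherins fell, with medians of -1.73, -1.47 and -1.6 and camera adjusted p of 2.06e-104, 4.04e-68 and 2.94e-35, or 0.000139, 0.00299 and 0.000451 with an estimated correlation. Pcdha12, Pcdhb22 and Pcdhga2 had log2 fold changes of -2.7, -2.37 and -2.22. Of 32 Hox genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.00022, adjusted p = 0.0143 with an estimated correlation), with Hoxb5 at 0.8 and Hoxa9 at 0.59. Of 24 interferon response genes 9 rose (18 adjusted over the list alone), 23 were higher in KO, and the median was 0.68. Ifit1 was 37.9 ± 9.24 against 14.8 ± 4.86 CPM (log2 1.35, SE 0.265, adjusted p = 0.0102) and the interferon regulator gene Irf7 rose 2.3-fold (adjusted p = 0.00275). The list gave 6.58e-15, and adjusted p = 0.108 with an estimated correlation. The number of members called was 4, 5 and 6 without crush WT library 1, crush KO library 1 and crush KO library 3, with the median at 0.586 or above. Rsad2 rose 2.75-fold (adjusted p = 0.0247), a call lost without crush WT library 1 or 3 or crush KO library 3 (0.074, 0.08 and 0.079), and Usp18 rose 2.09-fold (0.0162), a call lost without crush WT library 1 or 3 or crush KO library 1 (0.0638, 0.0542 and 0.067). Macrophage and immune genes had 0 of 16 called, a median of -0.34 and a camera adjusted p of 0.0608.

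Of 42 regeneration-associated genes 9 fell and 1 rose in KO after crush (11 and 2 adjusted over the list alone), with a median of -0.24, 8.94e-07 by camera and adjusted p = 0.653 with an estimated correlation. Sez6l was 27.2 ± 4.72 against 196 ± 28.5 CPM (log2 -2.85, SE 0.18, adjusted p = 2.71e-06), and Ecel1 and Sema6a had -1.78 and -1.83. Axon guidance (10 of 36 fell and 1 rose, 16 and 1 adjusted over the list alone), potassium channels (7 of 32 fell and 1 rose, 10 and 2), neuropeptides (5 of 14 fell, 5 and 1 up) and peptidergic nociceptor genes (4 of 12 fell, 7 and 2 up) gave 1.51e-06, 0.000107, 0.000107 and 4.94e-06, and adjusted p = 0.108, 0.569, 0.37 and 0.247 with an estimated correlation. Crh, Sst (somatostatin), Penk (the enkephalin precursor) and Tac1 had -3.9, -3.73, -1.47 and -1.47, and Kcnd2 and Kcnq3 had -2.42 and -2.19. The pruriceptor list (4 of 12 fell, 5 fell and 1 rose adjusted over the list alone) gave 0.0101, adjusted p = 0.283 with an estimated correlation and 0.118 without crush KO library 3; Mrgprx1 had -1.02. Large-diameter genes (3 of 15 fell, 3 adjusted over the list alone) gave 0.00668, adjusted p = 0.653 with an estimated correlation, and 0.172 and 0.109 without crush WT library 2 and crush KO library 3. Among synaptic adhesion genes, which had no camera call (0.359), Lrrtm3 fell by 0.87 and Lrrtm2 rose by 0.82 on the log2 scale. The other lists gave no camera call either.

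In naive animals, 69 genes rose and 442 fell in KO of 17880 tested, of which 28 and 205 changed at least 2-fold. Lypd1 was 0.384 ± 0.137 against 18.1 ± 3.16 CPM (log2 -5.54, SE 0.264, adjusted p = 1.99e-05), Kcnf1 was 0.824 ± 0.117 against 23.0 ± 9.37 (log2 -4.79, SE 0.379, adjusted p = 0.00027) and Calb1 was 2.06 ± 0.38 against 21.2 ± 2.88 (log2 -3.36, SE 0.19, adjusted p = 5.2e-05). Hal, Mrgprb5, Insm1 and Insrr had -3.59, -3.46, -3.13 and -2.92. Chia1 rose 3.12-fold, the metalloprotease gene Adamts8 2.47-fold and Aaed1 2.17-fold (adjusted p = 0.00239, 0.000941 and 0.000432). Ecel1 rose from 0.309 ± 0.239 to 3.66 ± 1.82 CPM (adjusted p = 0.0101), a call lost without naive WT library 3 (0.095). Without WT library 1 or 3 the count was 325 or 199 genes, and without KO library 1 or 2 it was 310 or 340. Without a low-count filter it was 1415.

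Of the naive protocadherins, 13 of 21 beta (19 adjusted over the list alone), 10 of 22 gamma (19) and 9 of 12 alpha (10) fell, with medians of -1.52, -0.9 and -1.82. Camera gave 2.02e-42, 8.06e-23 and 2.51e-30, and 0.0334, 0.0695 and 0.00983 with an estimated correlation. Pcdha12, Pcdha9, Pcdhb21 and Pcdhga3 had log2 fold changes of -2.61, -2.6, -2.16 and -1.81. Of 30 Hox genes 4 rose and 1, Hoxd1, fell (12 and 1 adjusted over the list alone, camera adjusted p = 8.34e-07, adjusted p = 0.0334 with an estimated correlation). Pruriceptor genes (7 of 12 fell, 9 adjusted over the list alone, median -0.86) gave 1.7e-16, and adjusted p = 0.0334 with an estimated correlation. Sst was 0.437 ± 0.146 against 5.22 ± 1.01 CPM (adjusted p = 0.000487), and Th had -1.11. Neuropeptides (3 of 10 fell, 7 adjusted over the list alone), sensory channels (7 of 32, 9), potassium channels (9 of 32, 15), nonpeptidergic (2 of 12, 5) and peptidergic nociceptors (4 of 12, 7) and large-diameter genes (2 of 15 fell, 7 fell and 1 rose) gave 9.29e-11, 6.03e-09, 5.25e-15, 2.57e-05, 6.05e-10 and 1.76e-06, and adjusted p = 0.0982, 0.158, 0.0982, 0.263, 0.245 and 0.266 with an estimated correlation. Tac1, Cnr1, Kcnd2 and Kcnq3 had -1.04, -1.67, -2.57 and -1.6. Axon guidance (5 of 35 fell, 6 adjusted over the list alone, Plxna2 at -1.23) gave 1.3e-05, and adjusted p = 0.259 with an estimated correlation. Synaptic adhesion (4 of 33 fell and 1 rose, 8 and 2 adjusted over the list alone, Lsamp at -0.77) gave 0.0434, adjusted p = 0.405 with an estimated correlation, and 0.0538, 0.0727 and 0.116 without WT library 1, KO library 1 and KO library 3. Neurotransmitter release (2 of 28 fell, 3 fell and 1 rose adjusted over the list alone, Cplx2 at -1.06) gave 0.0217, adjusted p = 0.607 with an estimated correlation and 0.0795 without KO library 3. Regeneration-associated genes went both ways (1 of 36 up and 2 down, 2 and 4 adjusted over the list alone, camera adjusted p = 0.493), Sox11 among those that fell (log2 -0.84, adjusted p = 0.00438). Interferon genes gave 0.642.

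The KO effects shared genes across conditions, from separate libraries. Of genes called, 452 fell and 128 rose both after sham and after crush, against 21.9 and 3.7 for independent lists. Sham and naive shared 318 that fell and 45 that rose, against 15.3 and 0.7, with 1 called in opposite directions. In all 3 conditions 246 genes fell and 39 rose. A direct test of the KO effect after sham against that in naive animals called 0 genes up and 3 down with edgeR, with 831 at an unadjusted p under 0.05. They were Ecel1 (log2 difference -5.26, SE 0.598, adjusted p = 0.00191), Sez6l (-1.78, SE 0.24, adjusted p = 0.0106) and Gm29374 (ENSMUSG00000099839, chromosome 1, 87142874 to 87146983; -4.96, SE 0.717, adjusted p = 0.017). Gm29374 lies next to Ecel1 (ENSMUSG00000026247, chromosome 1, 87147655 to 87156521) on the same strand, was chosen after its values were seen, and is uncertain as a separate gene.

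**Figure D4:**
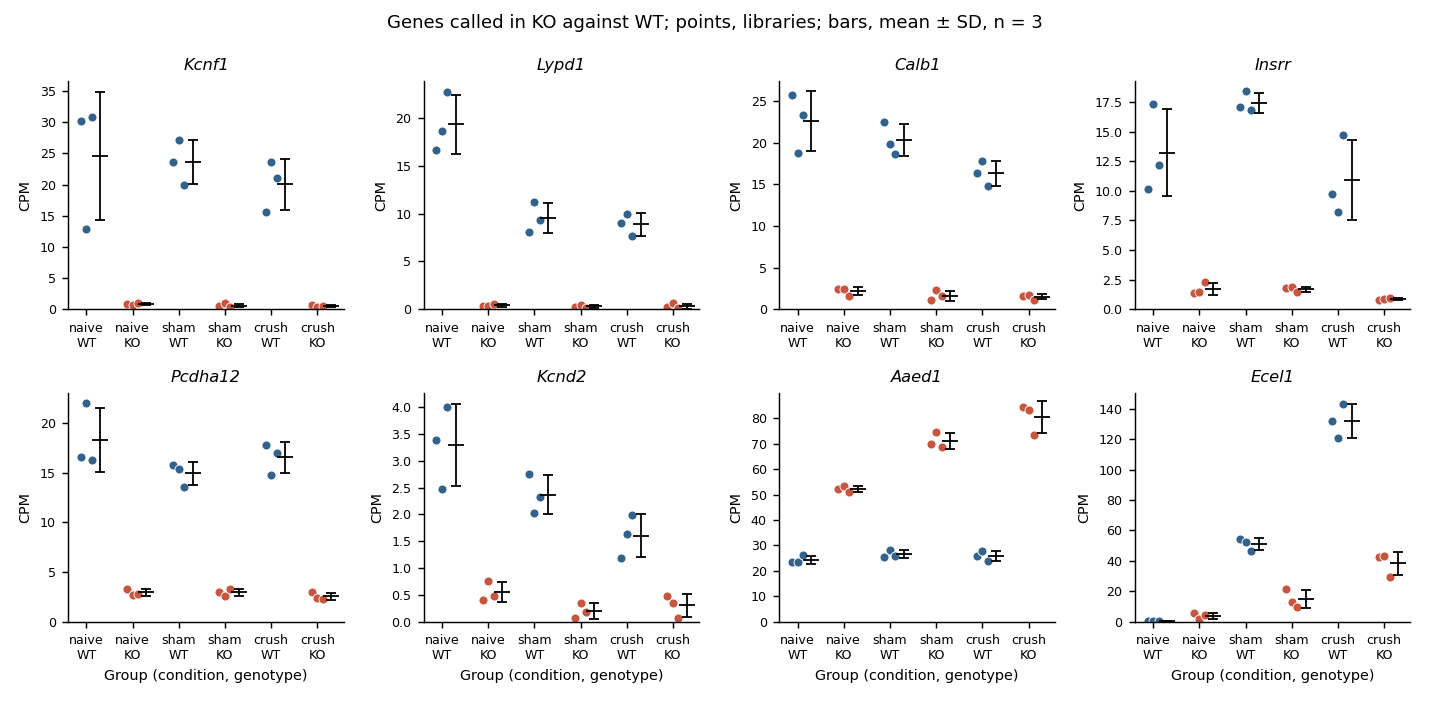
Level in CPM of TMM-scaled totals (y axes) of 8 genes in all 6 groups (x axes); points are libraries and bars give the mean and SD of 3. Kcnf1, Lypd1, Calb1, Insrr, Pcdha12 and Kcnd2 are lower and Aaed1 is higher in KO in every condition, while Ecel1 is higher in naive KO and lower in sham and crush KO than in WT.

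Sham was compared with naive to describe what surgery without nerve crush does, as a secondary comparison in which surgery and any difference of preparation cannot be told apart. Some injury genes were higher in sham WT. Npy had 381 counts over the 3 sham libraries and 0 over the 3 naive ones, at least 53.8-fold higher against a floor of 3 counts over the group. Sprr1a had 1966 against 2 counts, a ratio of 416 (95% counting interval 115 to 3440). Ecel1 was 50.8 ± 3.61 against 0.331 ± 0.259 CPM (log2 7.17, SE 0.445, adjusted p = 8.38e-08), Atf3 was 47.8 ± 12.9 against 4.27 ± 0.226 CPM (log2 3.48, SE 0.354, adjusted p = 9.44e-06), and Slc6a4, Gpr151, Gal and Gadd45a rose 30.6, 6.8, 6.48 and 2.0-fold. In KO, Npy had 581 against 2 counts (ratio 145, interval 40.1 to 1200), and Gpr151, Gal, Atf3 and Sox11 rose 9.02, 6.21, 5.46 and 2.7-fold. Regeneration-associated genes rose (25 of 43 up and 2 down in WT, 18 and 2 in KO, the same counts adjusted over the list alone), with medians of 0.7 and 0.46 and camera adjusted p of 1.94e-09 and 4.61e-06, or 0.479 and 0.627 with an estimated correlation. The injury transcription factors did not move as a list (6 of 26 up and 9 down in WT, 4 and 7 in KO, camera adjusted p = 0.242 and 0.453). With the intronic share as a covariate the medians were 1.44 and 0.9, with 37 and 35 of 43 members up. By Xist and Ddx3y each naive library was of 1 sex and each sham library held both, so sex differs with surgery here.

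Markers of other cells were lower in sham than in naive. In WT, 13 of 16 macrophage, 11 of 12 fibroblast, 12 of 14 endothelial and mural, 11 of 14 satellite glia and 10 of 13 Schwann genes fell (14, 12, 12, 11 and 11 adjusted over the list alone) and 1 Schwann gene rose, with list medians of -1.17, -1.09, -1.06, -1.04 and -0.9. Camera gave 5.55e-07, 1.69e-07, 5.55e-07, 1.1e-06 and 0.00248, and adjusted p = 0.427, 0.427, 0.427, 0.427 and 0.553 with an estimated correlation. Apoe, a satellite glia gene, was 262 ± 42.8 against 1100 ± 164 CPM (log2 -2.07, SE 0.276, adjusted p = 5.71e-05), and Col1a1, Acta2, Cx3cr1, Cd74 and Sox10 had -2.07, -2.27, -2.17, -1.78 and -1.3. In KO these lists had 12, 11, 12, 11 and 11 members down (13, 12, 12, 12 and 12 adjusted over the list alone), with camera adjusted p of 4.77e-06, 1.57e-07, 3.66e-06, 3.14e-06 and 0.0024, and adjusted p = 0.433, 0.433, 0.433, 0.433 and 0.627 with an estimated correlation. H19 and Cebpb had -2.36 and -2.27 in WT and -2.34 and -2.3 in KO, and Igfbp7, Apoe and Sox10 had -2.09, -1.92 and -1.17 in KO. The intronic share was higher in every sham library (0.746% or more) than in every naive library (0.687% or less). With it as a covariate 5 macrophage, 3 fibroblast, 6 endothelial and mural, 5 satellite glia and 1 Schwann genes fell in WT and 5, 5, 6, 6 and 1 in KO, with medians of -0.7, -0.71, -0.8, -0.73 and -0.72 in WT.

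Immediate early genes fell (11 of 15 in WT and 9 in KO; 12 and 9 adjusted over the list alone), with 5.11e-05 and 0.000374 by camera, and adjusted p = 0.427 and 0.433 with an estimated correlation. Klf2 and Egr1 had -1.96 and -1.57 in WT. Potassium channels (18 of 32 down and 2 up in WT, 18 and 3 in KO; 18 and 2, and 20 and 3, adjusted over the list alone) gave 5.55e-05 and 7.21e-05 (6 and 8 down, with medians of -0.06 and -0.09 against -0.41 and -0.52, with the intronic share as a covariate), large-diameter genes (10 and 9 of 15 down, 11 and 10 adjusted over the list alone) gave 0.000416 and 9.06e-05, axon guidance (12 of 36 down and 3 up in both, 13 and 12 down and 3 up adjusted over the list alone) gave 0.00694 and 0.00733, and cohesin genes (8 of 15 up and 1 down in WT, 10 up in KO, 9 and 1, and 10, adjusted over the list alone, Stag1 at 0.72 in WT) gave 0.0105 and 0.000701. With an estimated correlation their adjusted p was 0.479 and 0.564, 0.479 and 0.513, 0.491 and 0.608, and 0.427 and 0.433. In WT alone nonpeptidergic nociceptors (8 of 12 down and 1 up, 10 and 1 adjusted over the list alone, 0.00487), neurotransmitter release (11 of 28 down and 1 up, 11 and 2, 0.0123) and beta protocadherins (9 of 21 up, 9, 0.0463) passed camera, and adjusted p = 0.51, 0.61 and 0.599 with an estimated correlation. The beta protocadherin call was lost without naive library 1 or 3 (0.0872 and 0.0661) or sham library 1, 2 or 3 (0.0612, 0.0522 and 0.0666). In KO alone mitochondrially encoded genes did (6 of 10 down, 7 adjusted over the list alone, 0.0139, adjusted p = 0.665 with an estimated correlation). Whether these lists differ between genotypes was not tested for them. Sst had -2.67 in WT. In all, 5336 genes rose and 4967 fell in WT, and 4441 and 4472 in KO, with 3646 up and 3640 down in both (1018 and 954.2 for independent lists). Without naive WT library 1 the WT count was 6801, and without sham KO library 3 or naive KO library 1 the KO count was 5870 or 5473. With the intronic share as a covariate 5401 genes were called in WT, and with all libraries numbered 1 left out 1804 in WT and 1261 in KO.

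The H3K27ac lists were compared to ask whether this mark of active promoters and enhancers differs after crush in WT. The crush list held 15642 peaks over 158.0 Mb and the sham list 14338 over 207.3 Mb, without replicate lists to test. A peak in 1 list only may lie below the other list's cut, so it is not shown to be absent there. Of crush peaks, 13385 (85.6%, exact interval 85.0 to 86.1%) overlapped a sham peak, and of sham peaks 11159 (77.8%, 77.1 to 78.5%) overlapped a crush peak. Shares fell to 51.5% and 56.1% with a reciprocal overlap of 50%. Of the 745 genes that rose with crush, 200 (26.8%, 23.7 to 30.2%) had a crush-only peak within 50 kb, against 15.7% of other tested genes (odds ratio 1.97, Fisher's exact p = 2.2e-14), and 13.4% had a sham-only peak against 20.0% (odds ratio 0.62, Fisher's exact p = 5.33e-06). Of the 354 genes that fell, 36 (10.2%) had a crush-only peak against 16.1% (odds ratio 0.59, Fisher's exact p = 0.00167), and 24.3% had a sham-only peak against 19.7% (odds ratio 1.31, Fisher's exact p = 0.0368). The last was lost with a 100 kb window (odds ratio 1.23, Fisher's exact p = 0.0667), when only genes with a peak in the window were compared (1.26, 0.0938) and when peaks of any set of crush counted (1.3, 0.0534). Genes are not independent replicates. A reference peak lay within 1 kb of the start site of 43.0% of genes that rose, 43.2% of those that fell and 30.0% of others in the crush list, and of 35.3%, 48.6% and 32.1% in the sham list. Among 2198 genes raised by the average injury effect, the 489 with a crush-only peak had a median interaction of 0.041 and the other 1709 of 0.048, a difference of -0.007 (permutation p = 0.583 over 100000 resamples). The difference was -0.028 with a 100 kb window (permutation p = 0.0169) and 0.017 with 10 kb (permutation p = 0.348).

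**Figure D5:**
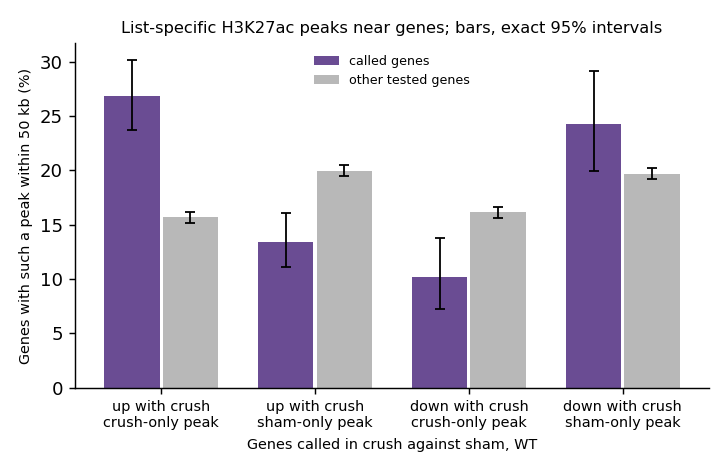
Percent of genes with a crush-only or sham-only H3K27ac peak within 50 kb of the start site (y axis) for genes called up or down with crush in WT and for other tested genes (x axis); bars give the percent and error bars exact 95% intervals. Crush-only peaks (not overlapped by a listed sham peak) lie near 26.8% of genes that rose and 15.7% of other genes.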

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

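The tests of unspliced RNA, of immune cell nuclei, of reads shared within the Ifit family, of nuclei of other cell types and of the preparation of naive libraries, and the intronic share as a covariate, were chosen only after the results were seen. Lists were singled out because camera on the genotype by injury interaction gave different effects of crush in WT and KO. Interferon genes differed with an adjusted p of 2.31e-08 (larger response in KO, 22 of 24 members). Immediate early genes (0.0306), macrophage genes (0.0306) and endothelial and mural genes (0.0329) differed toward a smaller rise in KO, and potassium channels (0.0306), large-diameter genes (0.0388) and the pruriceptor list (0.0495) toward a smaller fall in KO, with 12 of 15, 13 of 16, 12 of 14, 21 of 32, 12 of 15 and 9 of 12 members in that direction. With an estimated correlation the adjusted p was 0.934 for each of the 7, and with fry 0.915. With the replicate block it was 3.85e-06 for interferon, 0.0283 for immediate early, 0.0427 for macrophage, 0.0296 for endothelial, 0.000813 for potassium channel, 0.00922 for large-diameter and 0.0427 for pruriceptor genes. The potassium channel median was 0.15, and 0.06 with the intronic share as a covariate. Without 1 library the adjusted p of interferon genes ranged from 3.9e-15 to 0.00206, and the other 6 calls were lost without single libraries. Immediate early genes lost theirs without sham WT library 1 (0.187), crush WT library 2 (0.0831), sham KO library 1 (0.0526) or 2 (0.235), or crush KO library 2 (0.151) or 3 (0.113). Potassium channels did without sham WT library 1 (0.187), crush WT library 3 (0.396), sham KO library 1 (0.116) or 3 (0.0799), or crush KO library 1 (0.0778) or 2 (0.201). The pruriceptor list did without sham WT library 1 (0.146) or 3 (0.148), crush WT library 1 (0.0554) or 2 (0.254), sham KO library 1 (0.0526) or 2 (0.102), or crush KO library 1 (0.159) or 2 (0.161). Large-diameter genes did without sham WT library 1 (0.212) or 2 (0.1), crush WT library 1 (0.0554) or 3 (0.489), sham KO library 1 (0.35) or 3 (0.0999), or crush KO library 1 (0.0974) or 2 (0.201). Macrophage genes did without sham WT library 1 (0.234), crush WT library 1 (0.0748) or 2 (0.0831), sham KO library 2 (0.657, direction reversed), or crush KO library 2 (0.0879) or 3 (0.0696), and endothelial genes without sham WT library 1 (0.598), crush WT library 2 (0.0831) or 3 (0.28), sham KO library 2 (0.457) or crush KO library 2 (0.238).

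The effect of KO differed between sham and naive animals for Ecel1, Sez6l and Gm29374 (edgeR adjusted p = 0.00191, 0.0106 and 0.017). Ecel1 was higher in KO than in WT in naive animals (log2 3.48) and lower after sham (log2 -1.79). Gm29374 lies next to Ecel1 on the same strand, and whether reads running past one gene count for the other was not tested. The naive call of Ecel1 was lost with the intronic share as a covariate.

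Interferon genes were higher in KO than in WT after crush. More immune cell nuclei in KO would raise macrophage genes, and their median was -0.339, with Cd74 at 25.7 ± 1.71 against 23.1 ± 0.913 CPM and Mrc1 at 18.3 ± 1.07 against 25.2 ± 0.548 CPM in nuclei isolated by a neuronal mark. A single library was not the source, since the median stayed at 0.586 or above without each, and with the intronic share as a covariate it was 0.677. Reads shared within the Ifit family would raise its members alone, and the 20 other members had a median of 0.679. With an estimated correlation the camera call after crush was lost (adjusted p = 0.108), so an effect of genotype is a hypothesis.

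Libraries of a group differed along 1 axis that held 62.3% of the variance within groups over the 12 sham and crush libraries (11739 genes). It followed the intronic share (Pearson r = 0.97, exact permutation p = 0.000772, the smallest that 1296 permutations allow, adjusted over 2 relations 0.00154; rho 0.97, p = 0.000772; r = 0.96 without the 2 farthest libraries). For library depth r was -0.62 (exact permutation p = 0.0664; rho -0.63, p = 0.0509; r = -0.48 without the 2 farthest), which leaves depth open. Growth cytoskeleton (median loading -1.92 SD), neuropeptide (-1.88), mitochondrially encoded (-1.74), regeneration-associated (-1.52), neurotransmitter release (-1.5) and nonpeptidergic nociceptor genes (-1.5) lay at the low end. No biological explanation was tested.

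Regeneration-associated genes were higher in sham than in naive WT. Thinning to 13951578 counts gave a median of 0.697 and 23 called members, but it keeps expected folds, so depth stays open. Fewer nuclei of other cells would raise pan-neuronal genes, whose median was -0.329, but 0.254 with the intronic share as a covariate (6 of 16 up), while markers of other cells fell in both fits, so this stays open. The naive libraries may have been prepared apart: the highest naive total, 20.1 M counts, lay under the lowest sham total, and the intronic share did not overlap either, so surgery and preparation cannot be told apart.

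Splits of 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split of crush against sham in WT gave 1099 genes and the highest other 0. KO against WT gave 919 after sham (highest other 1), 1103 after crush (highest other 1) and 511 in naive (highest other 0), and sham against naive gave 10303 in WT and 8913 in KO (highest other 0). For crush against sham in KO, 2 of 10 splits gave as many as 1249, the other one 1927. That split sets sham KO libraries 1 and 3 and crush KO library 3, the 3 with the highest intronic share, against the rest, and points to a structure of the samples. With the intronic share as a covariate crush against sham in KO gave 1976 genes. For the interaction the real split gave 0 genes, so all 100 of the splits drawn give as many and their number decides nothing (highest other 44).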

How the results depend on the processing

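The intronic share as a covariate, leaving out all libraries with the same number, peaks found in both further sets or compared with any set, the paired regeneration-associated score and the genotype test on genes called in WT alone were chosen only after the results were seen; the cause of a change was not tested unless stated. Of 226 named gene results none reversed. All 226 kept their side of the threshold with DESeq2 size factors and a non-robust dispersion, 225 of 225 with at least 1 CPM in 3 libraries, 218 with DESeq2 (8 gained a call), 213 with the covariate (5 lost), 215 with the replicate block (3 lost), 224 without a low-count filter, 184 of 189 with only the 6 libraries compared, and 217 without each library in turn. Calls lost with the covariate include Egr1 (sham against naive WT), Ecel1 (naive) and Rsad2. With all libraries numbered 1, 2 or 3 left out, 120, 192 and 221 kept their side of the threshold, with 2 libraries per group. Of 240 list results 151 kept their side of the threshold with an estimated correlation, 199 with fry and 218 with the block. In 25 of the 240 the median, mean and camera differed in sign, and 0 of these 25 passed camera. Depth limits low genes most in the naive libraries.

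Counts of genes changed follow in the order crush against sham in WT (1099) and KO (1249), interaction (0), KO against WT after sham (919), crush (1103) and naive (511), and sham against naive in WT (10303) and KO (8913). The replicate block gave 4193, 6576, 46, 2549 and 2756 for the first 5. DESeq2 gave 1795, 2297, 34, 1437, 1728 and 812 for the first 6. The covariate gave 3385, 1976, 58, 2590, 3453, 851 and 5401 for the first 7; of the sham against naive calls 2650 of 10303 in WT and 3439 of 8913 in KO kept theirs. With libraries numbered 1 left out the counts were 9, 36, 123, 171, 302, 1804 and 1261 (interaction unchanged). Without those numbered 2 they were 252, 354, 355, 415 and 190 for crush in WT and KO and KO against WT after sham, crush and naive. Without those numbered 3 they were 2080 (crush in KO), 1 (interaction) and 283 (naive). At least 2-fold, by construction fewer, were 472, 560, 492, 569, 233, 4257 and 3533 (interaction 0). Only the 6 libraries compared gave 574 (crush in KO) and 671 (KO after crush), other libraries in the fit gave 2 for the interaction, and no low-count filter gave 1415 in naive. Without 1 library the ranges were 529 to 1290, 520 to 2369, 0 to 3, 452 to 851, 596 to 976, 199 to 588, 6801 to 10051 and 5473 to 9867.

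The numbers did not pair libraries elsewhere: same-numbered deviations correlated at -0.03, 0.36 and 0.73 for crush in KO (2 of 3 pairs best with their own number), 0.04, 0.4 and 0.81 for KO after crush (1), 0.64, -0.43 and 0.15 in naive (1; library 1 is male and 2 and 3 female in both genotypes by Xist and Ddx3y, so the number carries sex there, and the block gave 396 genes), -0.13, -0.52 and -0.08 for sham against naive in WT (0) and -0.13, 0.58 and 0.65 in KO (2). In the comparisons taken as paired, crush in WT and KO after sham, the block ended the call of Atp6v0c-ps2 after sham (edgeR adjusted p = 0.0526). Other named gene and list calls changed only as given beside the results. List member counts moved too. In the interaction, not paired in all groups, the block added calls for regeneration-associated (0.0394), pan-neuronal (0.0427) and neurotransmitter release genes (0.00922). With an estimated correlation 0, 0, 0, 5, 4, 4, 0 and 0 lists passed, and with fry 0 in the interaction. Lists past the threshold in the interaction ranged from 1 to 9 without 1 library.

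List results that reversed had no call before or after, apart from macrophage genes in the interaction, whose adjusted p without 1 library ranged from 3.59e-06 to 0.657, the latter without sham KO library 2. With fry they were the pruriceptor list (0.967) and axon guidance (0.967) for crush in KO, macrophage (0.946) and endothelial genes (0.974) for KO after sham and neurotransmitter release (0.923) for KO after crush. With the replicate block they were axon guidance for crush in KO (0.884), Schwann genes in the interaction (0.992), macrophage (0.993) and cohesin genes (0.915) for KO after sham, neurotransmitter release for KO after crush (0.804) and alpha protocadherins for sham against naive in KO (0.985). The injury score difference was -0.282 with genes called in WT alone (exact permutation p = 0.115), against 0.344 with those called in KO alone, where the choice of genes by 1 genotype favours that genotype, and -0.043 to 0.192 without 1 library. The regeneration-associated difference ranged from -0.226 to 0.088 without 1 library, and paired by replicate number it was -0.066 (exact permutation p = 0.5, smallest possible 0.25). Shared peaks were 51.5% (crush) and 56.1% (sham) with a reciprocal overlap of 50%, 84.6% (crush) in the upper part by signal and 81.3% (sham) among peaks in both further sets. The odds ratio of sham-only peaks near genes that fell was 1.23 with 100 kb, 1.26 among genes with a peak in the window and 1.3 against any set. The genotype difference at genes with crush-only peaks was 0.017 with 10 kb, -0.028 with 100 kb (permutation p = 0.0169) and 0.019 with genes called in WT alone.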

Other observations

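The test of a weaker regeneration-associated response in KO was chosen only after the result was seen. Sex chromosome transcripts differed between naive and operated libraries. In naive WT and KO library 1 Xist, from the inactive X of females, was at 0.1 and 0.61 CPM of the deposited total. Ddx3y, of the Y chromosome, was at 30.81 and 33.54 CPM. The other 4 naive libraries had 0 CPM of Ddx3y and 697.74 to 1197.64 CPM of Xist. All 12 sham and crush libraries held both, with Ddx3y from 13.27 to 37.5 CPM and Xist from 952.61 to 2574.42 CPM. Xist was lowest in a WT and highest in a KO library of each operation, so sex may differ with genotype. The labels do not state whether naive libraries came from single animals and the others from pools of both sexes.

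A hypothesis was that KO reduces the induction of regeneration-associated genes by crush. The score difference of -0.066 gave an exact permutation p of 0.845, which leaves it open.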
